A study of Mus musculus with 9 samples.

How the data were processed

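RNA sequencing libraries were made from the submandibular and sublingual salivary glands of female C57BL/6 mice aged 34 weeks. Per the labels, 3 libraries came from mice on chow (control), 3 from mice made obese by a diet with 60% of calories from fat, given from 4 weeks of age for 20 weeks (DIO), and 3 from DIO mice whose stomach was reduced by about 80% at 24 weeks of age (sleeve gastrectomy, SG). The labels name no sham operation and no diet for the weeks between surgery and collection, so SG differs from DIO by the operation, its fast and anaesthesia, and whatever diet followed. Nor do they give the diet of the DIO mice after those 20 weeks, so whether DIO glands were taken on the fat-rich diet is not known. The labels also do not say that each library came from a separate animal. The p-values here thus measure the spread between libraries, which may be technical in part.

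Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was sequenced, and libraries were built with the VAHTS Universal V6 kit. The submitters' processing notes name HISAT2, Salmon and the mouse genome build GRCm39, without versions or the role of each tool. The counting setting for strand, the annotation release and the rule for reads that match several genes are not given in the sources used here. The authors deposited a table of whole-number read counts per gene with no scaling, for 23256 genes of which 17509 are annotated in it as protein-coding. They also deposited an FPKM table of the same genes and libraries, that is, counts scaled by gene length and by library size. For every nonzero value the gene length implied by the count and the FPKM lay within 0.1% of that gene's median over libraries, so both tables hold the same quantification. Gene symbols and NCBI gene numbers were taken from the tables as given, and no genome coordinates are printed, because no annotation of GRCm39 was used here.

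The main test of each comparison was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with TMM scaling, edgeR's filter on low counts by group, and 1 fit of all 9 libraries in 3 groups, which share 1 estimate of the spread. The filter left 14912 genes, which held at least 99.8% of the counts of each library. P-values were adjusted by the Benjamini-Hochberg method over these genes with a threshold of 0.05, and every adjusted p given for a gene comes from this test unless another tool is named. Levels are CPM, counts brought to a common library total, on TMM-scaled library sizes, given as mean ± SD over 3 libraries, and SE is the standard error of the log2 fold change. The common biological coefficient of variation was 0.206, with 6 residual degrees of freedom and 4.90 prior degrees of freedom.

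Lists of genes for salivary cell types, metabolic pathways, stress responses, immune cells and tissues that could be cut out with the glands were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of the 38 lists, 36 had the minimum of 4 measured members. The list of mitochondrially encoded genes matched 0 symbols of the tables, and the sex check list held 1 measured gene, Xist, at 257 to 290 CPM in the group means. Each list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, which asks whether its genes differ more than the other genes tested, with Benjamini-Hochberg adjustment over the 36 lists. Camera with a correlation estimated from the data and fry, which asks whether the genes of a list move on balance to 1 side, stand beside it. Neither called a list in any of the 3 comparisons, whereas fry's test for change in either direction called 13 lists in DIO against control, 2 in SG against DIO and 4 in SG against control.

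The named genes followed this rule for each comparison. Among genes with an adjusted p under 0.05, a mean of at least 2 CPM in a group, no overlap between the groups and a symbol other than a clone or predicted name, the 8 with the largest fold change to each side were named, or all if fewer. If none passed, the 4 with the smallest p on each side were named as not passing. From each list called by camera, the 3 members with the smallest p were named. A panel of 14 genes was reported whatever its result, and other list members are given as members with their values. Some genes that these rules name are not reported here. For a count of genes changed in both DIO comparisons the rule took 10 genes, but that count was 0.

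Totals ran from 36349885 counts in DIO 2 to 43495564 in control 2, so that 3 counts, the floor used for detection, equalled 0.0690 to 0.0825 CPM. Floors and counts cover counting error only. The 10 most abundant genes of a library took 43.9% to 52.5% of its counts. Replicate libraries were compared by a chi-square test of their counts, which gave 30.3 to 230 per degree of freedom, so no library was a copy of another. Replicate numbers are shared by the groups, but nothing in the labels says that they mark pairs.

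On simulated counts drawn from the real means and library sizes, with genes changed by known folds, edgeR recovered 74 of 100 genes changed 2-fold and 84 of 100 changed 4-fold for DIO against control, with 12 false calls among 170. For SG against DIO it recovered 58 of 99 and 79 of 96, with 7 false calls among 144, and for SG against control 64 of 98 and 79 of 99, with 3 among 146. DESeq2 recovered 77 and 88 with 35 false calls among 200, 64 and 85 with 26 among 175, and 67 and 83 with 17 among 167. With no list changed, camera called 0, 1 and 0 of the 36 lists in these comparisons, and fry called 3, 0 and 0. A list raised 1.5-fold was called higher in all 3, also with an estimated correlation, and camera called 1, 2 and 1 other lists beside it. Genes were drawn independently, whereas correlations estimated within the real lists reached 0.97. The draws thus do not give the rate of false list calls in the real data, where regrouped libraries gave 9 to 23 lists.

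Reversal after surgery was measured as the genes called in both DIO against control and SG against DIO with opposite signs, and as the correlation of both fold changes across genes. Since both use the DIO libraries, 100 draws of unchanged groups that share them were simulated. The alternatives were DESeq2 1.42.0, RLE scaling, library totals without scaling, no filter on low counts and a stricter filter, fits of only the groups compared, a block for the replicate number, limma-trend on log2 FPKM with pseudocounts of 1 and 0.1, limma voom with sample weights, a minimum 2-fold change, leaving out the genes of neighbouring tissues, and leaving out each library in turn. Chosen after the data were examined were a robust fit, leaving out control 2 and SG 2 together, DESeq2 and the estimated correlation without control 2, and a covariate for lymphocyte genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

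Reads of near-identical genes could be split between copies in the counting. This applies to the kallikrein genes Klk1 and Klk1b, the exocrine gland peptide Esp8, the Scgb secretoglobins, the Dcpp, Amy1 and H2 genes, the interferon GTPases around Igtp, the globins Hba and Hbb, and Hspa8 and Hspa1a with Hspa1b, which have close copies or pseudogenes. Levels of overlapping genes and of antisense partners are uncertain as well, since the use of strand is not given.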

Results

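Gene expression was measured by RNA sequencing in submandibular and sublingual salivary glands of 34-week-old female mice fed chow (control, n = 3), made obese by a fat-rich diet (DIO, n = 3) or operated by sleeve gastrectomy after becoming obese (SG, n = 3). Libraries held 36349885 to 43495564 counts. Secretory genes dominated all of them, with Prol1, which encodes a proline-rich secreted protein, at 5.30% to 9.69% of the counts of a library. The first principal component held 35.4% of the variance, and control 2 stood apart from the rest. Its mean rank correlation with the other libraries was 0.973, against 0.985 to 0.987 for the other 8. Control 2 also held the highest level of Amy1, the salivary amylase gene of the parotid gland, at 8377 CPM against 1673 and 412 CPM in control 1 and control 3, 12.3 to 240 CPM in DIO and 11.8 to 1673 CPM in SG. Results are therefore given with and without that library where it matters.

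The comparison of DIO with control asks what diet-induced obesity does to gene expression in the glands. Of 14912 genes tested, 14 changed, 8 upward and 6 downward, and genes of the circadian clock stood among them. Dbp (NCBI gene 13170), a transcription factor of clock output, fell from 169 ± 22.3 to 57.4 ± 16.1 CPM (SD, n = 3 per group; log2 fold change -1.56, SE 0.21, adjusted p = 0.0333). Nr1d1 (217166), the clock repressor REV-ERB alpha, fell from 124 ± 3.97 to 45.4 ± 7.44 CPM (log2 fold change -1.45, SE 0.17, adjusted p = 0.0118). The clock repressor Bhlhe41 (79362) fell from 33.5 ± 2.87 to 17.9 ± 0.416 CPM (log2 fold change -0.90, SE 0.08, adjusted p = 0.00398).

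The largest change was in Zbtb16 (235320), a zinc finger factor induced by glucocorticoids, which rose from 3.47 ± 0.701 to 27.5 ± 3.64 CPM (n = 3 per group; log2 fold change 2.98, SE 0.45, adjusted p = 0.0437). The chaperone gene Hspa8 (15481) rose from 527 ± 58.5 to 1012 ± 141 CPM (log2 fold change 0.94, SE 0.13, adjusted p = 0.0333). Igtp (16145), an interferon-induced GTPase, rose from 10.4 ± 1.46 to 20.6 ± 3.19 CPM (log2 fold change 0.99, SE 0.15, adjusted p = 0.0437). Also higher were the carboxylesterase Ces1d (104158; log2 fold change 0.91, SE 0.12), the gland-secreted peptide Esp8 (100126778; 0.93, SE 0.14) and the scaffold protein Sash1 (70097; 0.54, SE 0.08). Lower were Dgki (320127), a diacylglycerol kinase that fell from 25.2 ± 5.14 to 6.85 ± 0.488 CPM (log2 fold change -1.88, SE 0.18, adjusted p = 0.00398), the kinase Nek10 (674895; -1.93, SE 0.28) and the Golgi protein Golph3l (229593; -0.67, SE 0.10).

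In each of these 14 genes all DIO libraries lay to the same side of all control libraries, as did 16.3% of all genes, where chance gives 10%. An unadjusted p under 0.05 was reached by 1537 genes against 745.6 expected of independent genes. A regrouping of the control and DIO libraries gave 2070, so 1537 is not beyond what regrouped libraries give. DESeq2 called 185 genes, 73 higher and 112 lower, which included the 14. The count was 140 without control 2, all 14 among them, and 17 without SG 1. It was 0 without DIO 1, 2 without control 3, 3 without control 1 or DIO 3, 4 without DIO 2 or SG 3, and 10 without SG 2. Dgki and Bhlhe41 passed in 8 of the 9 fits that left out a library, with a highest adjusted p of 0.0705, and Sash1 in 1. With library totals in place of TMM, the median of all genes moved to 0.10 on the log2 scale and the split of calls to 17 higher and 5 lower.

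**Figure D1:**
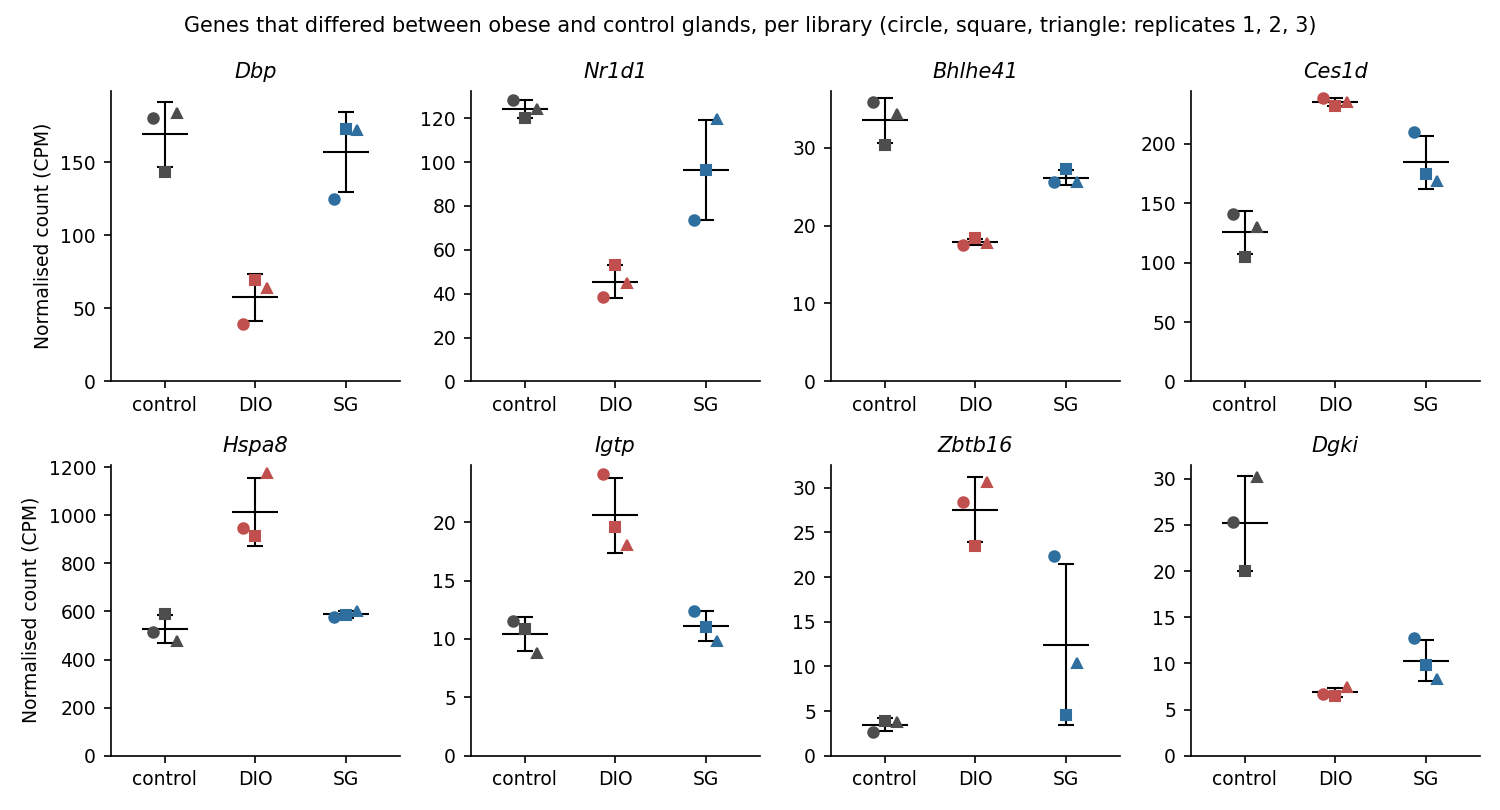
Normalised counts (CPM, vertical axis) of 8 of the 14 genes called in DIO against control, with 1 point per library, a bar at the mean and whiskers of 1 SD (n = 3). Dbp averaged 169 CPM in control, 57.4 in DIO and 157 in SG, and Dgki 25.2, 6.85 and 10.3.

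Interferon response and antigen presentation genes were higher in DIO than in control as groups. All 26 measured interferon response genes were higher, with a median log2 fold change of 0.46, and all 16 antigen presentation genes were higher, with a median of 0.59 (camera, adjusted p = 1.69e-15 and 1.41e-15). For both, adjusted p = 0.300 with an estimated correlation, and the range over the alternatives was 3.14e-20 to 0.316 for interferon genes and 1.45e-28 to 0.300 for antigen presentation genes. Among interferon genes Igtp passed over all genes tested, and 7 passed when adjusted over the list alone, among them Gbp2, Ifi27l2a, Irf1, Psmb8 and Rsad2. Ifi27l2a averaged 224 ± 23.6 CPM in DIO and 108 ± 14.8 in control (log2 fold change 1.05, SE 0.21, adjusted p = 0.116). Among antigen presentation genes 0 passed over all genes and 10 adjusted over the list alone, including the class I gene H2-K1, at 761 ± 120 and 474 ± 47.7 CPM, and the class II gene H2-Eb1, at 163 ± 14.3 and 98.0 ± 22.4 CPM. Leaving out any library kept both calls. Inflammatory cytokine and NF-kB genes were not called, with 10 higher and 14 lower of 24 members (median -0.06, with a test to the higher side, adjusted p = 0.737). They were called higher without control 2 (0.16).

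Macrophage and dendritic cell genes were higher in 20 of 25 members (median 0.37, camera adjusted p = 7.17e-07; adjusted p = 0.451 with an estimated correlation), and 6 passed adjusted over the list alone, 0 over all genes. Itgax, an integrin of dendritic cells, averaged 12.0 ± 1.90 CPM in DIO and 6.62 ± 1.11 in control. The median was 0.16 without control 3 and 0.64 without control 2. T and NK cell genes were higher in 15 of 24 (median 0.23, adjusted p = 0.00139; adjusted p = 0.622 with an estimated correlation), and 1, the granzyme Gzmk, passed adjusted over the list alone. This call rested on the control libraries, with a median of -0.22 without control 3, where the call was lost, -0.11 without control 1 and 2.13 without control 2. It was 0.05 without DIO 1, 0.06 without DIO 2 and 0.34 without DIO 3. The levels of B cell genes spread widely in control, 3.44 on the log2 scale above the gene means in control 2 and -3.20 in control 3, against 0.53 to 2.05 in DIO. Neither B cell genes (14 of 14 lower, median -0.56, adjusted p = 0.271) nor lymph node genes (-1.07, 0.398) nor plasma cell genes (0.35, 0.523) were called with all libraries. The B cell test pointed to the higher side, opposite to its median. Without control 2 their medians were 2.72, 2.14 and 0.99 and each was called higher, and without control 3 the B cell and lymph node medians were -1.13 and -1.75 and were called. Lymph node genes were also called without control 1 (-1.74).

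**Figure D2:**
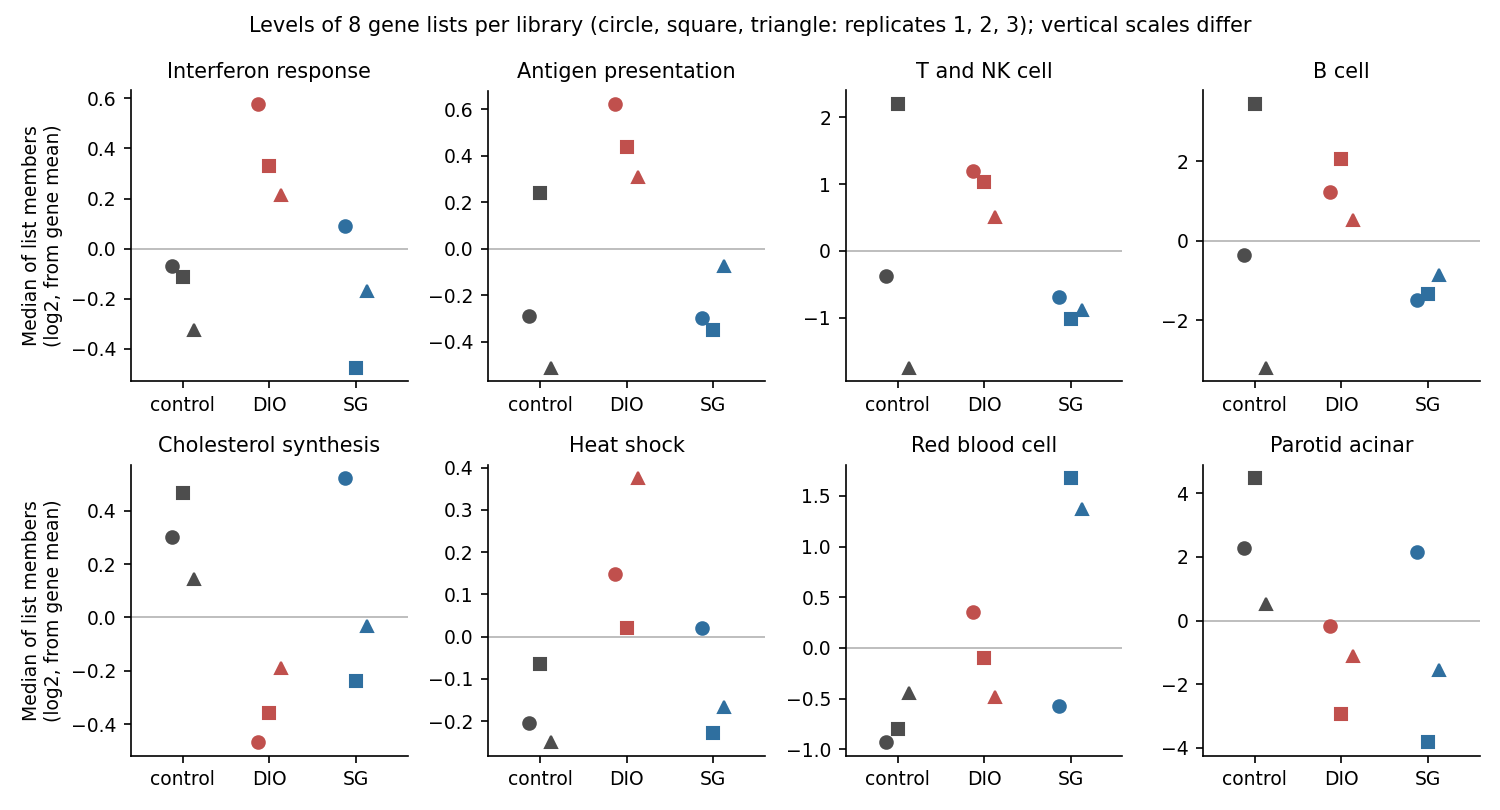
Level of 8 gene lists per library, as the median over list members of log2 CPM less the gene's mean over the 9 libraries (vertical axis, scales differ), with 1 point per library. Control 2 (square) stands highest in the B cell (3.44) and parotid (4.48) panels.

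Cholesterol synthesis genes were lower in DIO in 21 of 21 members (median log2 fold change -0.55, camera adjusted p = 1.32e-19; adjusted p = 0.300 with an estimated correlation, range over the alternatives 8.79e-32 to 0.316). No member passed over all genes and 11 passed adjusted over the list alone. Msmo1, a sterol oxidase, averaged 13.7 ± 0.638 CPM in DIO and 26.5 ± 4.29 in control, and Fdft1, the squalene synthase, 23.0 ± 3.51 and 39.5 ± 2.32 (n = 3). Each library left out in turn kept the call. Fatty acid and triglyceride synthesis genes were lower in 18 of 22 (median -0.26, adjusted p = 4.92e-05; adjusted p = 0.403 with an estimated correlation), with Acss2, Dgat2, Fasn and Slc25a1 past the threshold adjusted over the list alone. Fasn, the fatty acid synthase, averaged 73.8 ± 1.02 CPM in DIO and 117 ± 34.6 in control. Without control 2 this median was -0.08 and the call was lost (adjusted p = 0.0586). Adipocyte genes, a sign of fat tissue, stood highest in that library, at 1.79 on the log2 scale above the gene means.

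Heat shock genes were higher in 9 of 12 members (median 0.28, camera adjusted p = 1.05e-06; adjusted p = 0.300 with an estimated correlation, range over the alternatives 8.32e-11 to 0.316). Hspa8 passed over all genes, and Hspa1a, Hspa1b, Hspb1 and Hsph1 joined it adjusted over the list alone. Hsph1 averaged 49.9 ± 14.3 CPM in DIO and 25.6 ± 3.90 in control. The median was 0.18 without control 1 and 0.43 without control 2. Immediate early genes, which respond to handling, had a median of 0.21 (adjusted p = 0.0603) and were called higher without control 3, DIO 1, DIO 2 or SG 2, with medians of 0.46, 0.18, 0.39 and 0.19. Glucocorticoid-responsive genes had a median of 0.24 (adjusted p = 0.0775). Of these Zbtb16 passed over all genes, and Zbtb16, Fkbp5 and Map3k6 were higher and Mt1 and Mt2 lower adjusted over the list alone. That list was called higher without control 2, DIO 2 or SG 2, with medians of 0.26, 0.06 and 0.09.

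Clock genes went both ways, with 7 higher and 12 lower of 19 members. Over all genes 1 rose and 3 fell, and adjusted over the list alone 4 were higher (among them Clock, Nfil3 and Per2) and 3 lower (Bhlhe41, Dbp and Nr1d1). Nfil3, a repressor that acts against Dbp, averaged 42.0 ± 11.8 CPM in DIO and 21.0 ± 2.00 in control. As a list they had a median of -0.07 (camera adjusted p = 0.0447; adjusted p = 0.571 with an estimated correlation), which turned to 0.03 with library totals. This call was lost without control 1, control 3, DIO 1, DIO 3 or SG 2, with medians of -0.06, -0.06, -0.13, -0.09 and -0.09, while without control 2 the median was -0.23 and without DIO 2 it was -0.12.

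Genes of the granular ducts and kallikreins were higher in DIO in 17 of 19 members (median 0.47, camera adjusted p = 3.62e-07; adjusted p = 0.523 with an estimated correlation, range over the alternatives 4.01e-15 to 0.723). These ducts store growth factors and proteases in rodents. Klk1b1, Klk1b3, Klk1b4, Klk1b5 and Klk1b16 passed adjusted over the list alone and 0 over all genes. Klk1b4 averaged 513 ± 91.0 CPM in DIO and 296 ± 97.8 in control, Klk1b5 841 ± 145 and 526 ± 142, and the members share long stretches of sequence. The median was 0.71 without control 1 and 0.26 without control 2. Parotid acinar genes were lower in 7 of 7 (median -4.30, adjusted p = 1.67e-06; adjusted p = 0.300 with an estimated correlation), with 6 past the threshold adjusted over the list alone, among them Dnase1, at 24.5 ± 19.3 CPM in DIO and 483 ± 570 in control. Without control 2 the median was -2.71. Parotid genes may come from tissue of the neighbouring gland. Their level was 0.51 to 4.48 on the log2 scale from the gene means in control, -2.93 to -0.17 in DIO and -3.83 to 2.16 in SG. The amount of such tissue per library cannot be told apart from an effect of the diet here.

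Serous acinar genes, 5 of which also stand in the parotid list, had a median of -0.20 (camera adjusted p = 0.0043; adjusted p = 0.300 with an estimated correlation), with Creb3l1 and Prlr lower adjusted over the list alone, and -0.34 without control 2. Mucous acinar genes had a median of -0.35 (adjusted p = 0.0142; adjusted p = 0.451 with an estimated correlation), which was -0.06 without control 2 and -0.24 without DIO 3, both without a call. Duct and ionocyte genes had a median of 0.15 (adjusted p = 0.0203; adjusted p = 0.588 with an estimated correlation), 0.08 without control 2 and 0.10 without DIO 3, again without a call, and 0.08 without DIO 1. Foxi1, a factor of ionocytes, averaged 23.0 ± 2.89 CPM in DIO and 15.8 ± 2.02 in control. Myoepithelial genes had a median of -0.16 (adjusted p = 0.0306; adjusted p = 0.622 with an estimated correlation), with no call without control 1, control 2 or DIO 2 (medians -0.16, -0.19 and -0.05) and -0.26 without DIO 1.

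Among panel genes, Egf averaged 1056 ± 150 CPM in DIO and 808 ± 244 in control, Smgc, a mucin-like secreted protein, 4279 ± 498 and 2393 ± 1368, the mucin Muc19 1141 ± 336 and 1529 ± 588, the water channel Aqp5 604 ± 80.1 and 603 ± 62.9, and the muscarinic receptor Chrm3 46.9 ± 0.906 and 38.5 ± 2.41 (n = 3). Their adjusted p-values were 0.598, 0.561, 0.655, 0.995 and 0.257. Klk1, Adipoq, Scd1, Jchain, Cd68, Tnf, Col1a1 and Hspa5 did not pass either, with adjusted p-values of 0.580 to 0.992.

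Lists of other tissues also differed between DIO and control. Red blood cell genes were higher in 8 of 8 (median 0.79, camera adjusted p = 0.00239; adjusted p = 0.523 with an estimated correlation), 0.50 without DIO 1, with 1 member past the threshold adjusted over the list alone. Cell cycle genes were lower in 28 of 30 (median -1.54, adjusted p = 3.62e-07; adjusted p = 0.588 with an estimated correlation), but they stood highest in control 2, and without it the median was 0.02 and there was no call. Adipocyte genes were lower in 15 of 19 (median -0.50, adjusted p = 0.0139; adjusted p = 0.622 with an estimated correlation), with a median of 0.10 without control 2 and -0.27 without DIO 3, both without a call, and of -0.89, -0.75, -0.75 and -0.79 without control 1, control 3, DIO 1 and DIO 2. Endothelial genes were lower in 15 of 17 (median -0.22, adjusted p = 0.00139; adjusted p = 0.571 with an estimated correlation) and lost the call without control 2 (-0.13).

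Fibroblast and matrix genes had a median of -0.04 (camera adjusted p = 0.0203; adjusted p = 0.622 with an estimated correlation), which turned to 0.07 with library totals. 1 member passed adjusted over the list alone. The list lost its call without control 2, DIO 2 or DIO 3 (medians -0.02, -0.05 and 0.00) and had medians of -0.10, -0.11 and -0.22 without control 1, control 3 and DIO 1. Apoptosis genes had a median of 0.13 (adjusted p = 0.0487; adjusted p = 0.588 with an estimated correlation), and any library left out other than control 2 (0.21) and DIO 1 (0.08) ended the call, with medians from 0.02 without control 3 to 0.13 without SG 3. The 16 lists not called included those for fluid secretion (median 0.05), insulin signalling (-0.01), autophagy (0.04), oxidative stress (0.00) and nerve (0.20).

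The comparison of SG with DIO asks what sleeve gastrectomy changed in obese mice. No gene passed the threshold. Dbp averaged 157 ± 27.3 CPM in SG and 57.4 ± 16.1 in DIO (log2 fold change 1.45, SE 0.21), Nr1d1 96.5 ± 22.9 and 45.4 ± 7.44 (1.09, SE 0.17), and Bhlhe41 26.1 ± 0.997 and 17.9 ± 0.416 (0.55, SE 0.08; n = 3). Lower in SG were Hspa8 (587 ± 13.0 and 1012 ± 141 CPM; -0.79, SE 0.13), Igtp (11.1 ± 1.29 and 20.6 ± 3.19 CPM; -0.89, SE 0.15), the potassium channel Kcnk6 (52150; -0.70, SE 0.11) and the neuronal antigen Cdr2 (12585; -0.67, SE 0.11).

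Each of these genes had an adjusted p of 0.116, the smallest of the comparison in edgeR's quasi-likelihood test, where 1331 genes had an unadjusted p under 0.05. DESeq2 called 80 genes, 32 higher and 48 lower. Leaving out control 2 gave 117 genes, 18 higher and 99 lower, although that library belongs to neither group. A fit of these 2 groups alone gave 179, 21 higher and 158 lower.

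Interferon response and antigen presentation genes were lower in SG than in DIO as groups. All 26 interferon response genes were lower, with a median log2 fold change of -0.47, and all 16 antigen presentation genes, with a median of -0.68 (camera, adjusted p = 1.56e-16 and 9.11e-21). For both, adjusted p = 0.305 with an estimated correlation, and the range over the alternatives was 2.51e-21 to 0.305 and 1.09e-27 to 0.305. Adjusted over the list alone, 9 and 15 members passed, and 0 over all genes. The peptide transporter Tap1 averaged 19.9 ± 2.95 CPM in SG and 29.9 ± 3.29 in DIO (log2 fold change -0.59, SE 0.13). Without SG 2 the interferon median was -0.27, with the call kept. Inflammatory cytokine and NF-kB genes were lower in 15 of 24 (median -0.08, adjusted p = 0.0508) and were called without control 2 (-0.06), control 3 (-0.07), DIO 3 (-0.15) or SG 2 (-0.30).

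All 24 T and NK cell genes were lower in SG (median -1.98, camera adjusted p = 4.83e-15; adjusted p = 0.305 with an estimated correlation), all 14 B cell genes (-2.87, 1.01e-09; adjusted p = 0.346 with an estimated correlation) and all 9 lymph node genes (-1.45, 0.000171; adjusted p = 0.362 with an estimated correlation). These calls held with any library left out. Lymph node genes stood at 0.28 to 1.06 on the log2 scale from the gene means in DIO and at -1.04 to -0.77 in SG. Lymph node tissue taken with the glands could give such values. Its amount per library cannot be told apart from an effect of surgery here. Cd28, Gzmk and Nkg7 passed adjusted over the T and NK cell list alone, with Nkg7, a granule protein of cytotoxic cells, at 1.33 ± 0.133 CPM in SG and 3.82 ± 0.498 in DIO. The levels were low, with the B cell factor Pax5 at 0.127 ± 0.131 and 2.34 ± 1.63 CPM. Plasma cell genes had a median of -0.77 (adjusted p = 0.00101; adjusted p = 0.346 with an estimated correlation), where Jchain, Mzb1, Pou2af1 and Irf4 were lower and Pigr higher adjusted over the list alone. Macrophage genes were lower in 20 of 25 (median -0.25, adjusted p = 0.00101; adjusted p = 0.501 with an estimated correlation). Without SG 1 both these calls were lost, with medians of -0.66 and -0.17. Cell cycle genes were lower in 30 of 30 (median -0.45, adjusted p = 0.00192; adjusted p = 0.723 with an estimated correlation), -0.21 with no call without SG 3 and -0.25 without DIO 1.

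Cholesterol synthesis genes were higher in SG than in DIO in 20 of 21 members (median 0.37, camera adjusted p = 1.33e-11; adjusted p = 0.327 with an estimated correlation, range over the alternatives 3.31e-25 to 0.339). Fdft1, Msmo1 and Sqle passed adjusted over the list alone. Sqle, the squalene epoxidase, averaged 19.9 ± 7.02 CPM in SG and 10.4 ± 0.561 in DIO (log2 fold change 0.94, SE 0.21), with 28.0 CPM in SG 1. Without SG 1 the median was 0.15, with the call kept. Heat shock genes were lower in 10 of 12 (median -0.32, adjusted p = 1.05e-06; adjusted p = 0.305 with an estimated correlation), Hspa8 and Hsph1 adjusted over the list alone, and -0.17 without DIO 3.

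Glucocorticoid-responsive genes were lower in SG in 15 of 19 (median -0.49, camera adjusted p = 4.12e-07; adjusted p = 0.305 with an estimated correlation), with 9 lower and 1 higher adjusted over the list alone. Tsc22d3, a leucine zipper protein induced by glucocorticoids, averaged 41.0 ± 4.24 CPM in SG and 61.9 ± 4.21 in DIO (log2 fold change -0.59, SE 0.10, adjusted p = 0.187), and the clock gene Per1 66.6 ± 21.2 and 108 ± 12.9. Immediate early genes, a sign of handling at collection, were lower in 22 of 23 (median -0.57, adjusted p = 5.48e-10; adjusted p = 0.305 with an estimated correlation), with Btg2, Dusp1, Klf2, Nr4a2 and Nr4a3 adjusted over the list alone. Without DIO 3 that median was -0.28, and the glucocorticoid call held without any library.

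Red blood cell genes were higher in SG in 8 of 8 (median 1.16, camera adjusted p = 7.25e-06; adjusted p = 0.327 with an estimated correlation), with levels of 1.68 and 1.37 above the gene means in SG 2 and SG 3 and -0.58 in SG 1, and a median of 0.73 without SG 2. Endothelial genes were higher in 16 of 17 (median 0.29, adjusted p = 2.57e-05; adjusted p = 0.356 with an estimated correlation). Their median was 0.45 without SG 1, 0.19 without SG 2 and 0.15 without SG 3, and the endothelial cadherin Cdh5 averaged 11.4 ± 2.56 CPM in SG and 7.22 ± 0.970 in DIO. Tight junction genes were higher in 14 of 19 (median 0.14, adjusted p = 0.000936; adjusted p = 0.305 with an estimated correlation). Duct and ionocyte genes were higher in 18 of 23 (median 0.12, adjusted p = 0.00178; adjusted p = 0.362 with an estimated correlation), 0.09 with no call without DIO 2 and 0.07 without SG 3.

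Fatty acid oxidation genes were higher in SG in 17 of 23 (median 0.15, camera adjusted p = 0.00403; adjusted p = 0.362 with an estimated correlation), with no call without DIO 3 (0.12) or SG 2 (0.08). Respiratory chain genes had a median of 0.08 (adjusted p = 0.0452; adjusted p = 0.778 with an estimated correlation), with no call without control 1 (0.08), DIO 1 (0.03), DIO 2 (0.06), SG 2 (0.05) or SG 3 (0.07), and 0.18 and 0.13 without DIO 3 and SG 1. Skeletal muscle genes, which may come with neck tissue, were higher in 8 of 8 (median 1.17, adjusted p = 0.00489; adjusted p = 0.362 with an estimated correlation). SG 2 alone carried this, with the muscle actin Acta1 at 11.5 CPM against 0.152 and 0.278 in SG 1 and SG 3, and the median without it was -0.09 with no call, against 1.34 without control 3 and 1.80 to 2.48 without any other library. Parotid genes had a median of 1.75 (adjusted p = 0.303) and were called without SG 2 (2.35). Kallikreins had a median of 0.09 without a call and were called lower without SG 2 (-0.17) and higher without SG 3 (0.29). In the panel, Scd1, a fatty acid desaturase, averaged 89.5 ± 19.6 CPM in SG and 147 ± 3.17 in DIO (adjusted p = 0.554), Egf 1071 ± 253 and 1056 ± 150 (0.988), and Aqp5 643 ± 79.9 and 604 ± 80.1 (0.898), and the other panel genes had adjusted p-values of 0.470 to 0.984.

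The comparison of SG with control asks how far operated mice still differed from lean ones. No gene passed the threshold, and the smallest adjusted p was 0.0770 (edgeR's quasi-likelihood test). Dclk2 (70762), a kinase, had it at 0.561 ± 0.239 CPM in SG and 3.70 ± 0.224 in control (log2 fold change -2.72, SE 0.35; n = 3), as did Dgki (10.3 ± 2.23 and 25.2 ± 5.14 CPM; -1.29, SE 0.18). Lower without passing was also Tsc22d3 (14605; -0.65, SE 0.10, adjusted p = 0.220). The prolyl hydroxylase Egln3 (112407; 0.59, SE 0.11), the Wnt receptor Fzd6 (14368; 0.54, SE 0.11) and the cholesteryl ester hydrolase Nceh1 (320024; 0.43, SE 0.08) had adjusted p = 0.344. An unadjusted p under 0.05 was reached by 1208 genes, and DESeq2 called 54, 13 higher and 41 lower. The groups did not overlap in 11.8% of genes, where chance gives 10%. Leaving out SG 1 gave 6 genes, control 2 gave 3 and SG 3 gave 1.

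Lists of gland and blood genes were higher in SG than in control. Red blood cell genes were higher in 8 of 8 (median log2 fold change 1.79, camera adjusted p = 3.64e-16; adjusted p = 0.145 with an estimated correlation, range over the alternatives 4.98e-47 to 0.305), 7 of them adjusted over the list alone. The beta-globin Hbb-bs averaged 139 ± 104 CPM in SG and 29.1 ± 5.88 in control, with 36.7 CPM in SG 1 and 244 and 136 CPM in SG 2 and SG 3. Duct and ionocyte genes were higher in 20 of 23 (median 0.29, adjusted p = 1.03e-09; adjusted p = 0.289 with an estimated correlation), with Ascl3, Foxi1, Foxi2, Gsta4, Hepacam2, Krt7 and Scnn1b adjusted over the list alone. The ionocyte factor Foxi2 averaged 11.1 ± 1.69 CPM in SG and 6.16 ± 1.22 in control. Tight junction genes were higher in 18 of 19 (median 0.14, adjusted p = 2.56e-07; adjusted p = 0.145 with an estimated correlation). Leaving out any library kept these 3 calls.

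Kallikrein and growth factor genes were higher in SG than in control in 17 of 19 (median 0.62, camera adjusted p = 8.79e-11; adjusted p = 0.371 with an estimated correlation), 7 adjusted over the list alone, and 0.35 without SG 2. Klk1b3 averaged 151 ± 44.1 CPM in SG and 85.6 ± 25.3 in control. Fatty acid oxidation genes were higher in 18 of 23 (median 0.17, adjusted p = 0.000154; adjusted p = 0.371 with an estimated correlation), with Ucp3, a mitochondrial carrier, at 3.07 ± 0.850 and 1.03 ± 0.363 CPM and Acot2 past the threshold adjusted over the list alone. The call was lost without control 1 (0.13) or SG 2 (0.08). Respiratory chain genes were higher in 24 of 25 (median 0.12, adjusted p = 0.00026; adjusted p = 0.593 with an estimated correlation), with no call without control 2 (0.05), 0.18 without control 3 and 0.07 without SG 2. Skeletal muscle genes had a median of 1.34 (adjusted p = 0.0442; adjusted p = 0.521 with an estimated correlation), -0.25 without SG 2 and 1.45 without control 1, both without a call, and 2.29 without SG 3. Macrophage genes had a median of 0.13 and a mean of -0.08 with a test to the higher side (adjusted p = 0.0491; adjusted p = 0.639 with an estimated correlation), and the call was lost without control 1 (0.10), control 3 (-0.11), DIO 2 (0.11), DIO 3 (0.11), SG 2 (-0.02) or SG 3 (0.09), while without control 2 the median was 0.36.

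Fatty acid and triglyceride synthesis genes were lower in SG than in control in 20 of 22 (median -0.27, camera adjusted p = 1.26e-07; adjusted p = 0.301 with an estimated correlation), with Acss2, Dgat2, Fasn, Scd1 and Thrsp adjusted over the list alone, and no library left out ended the call. Scd1 averaged 89.5 ± 19.6 CPM in SG and 193 ± 112 in control (log2 fold change -1.11, SE 0.32, adjusted p = 0.528). Cholesterol synthesis genes had a median of -0.15 (adjusted p = 0.00435; adjusted p = 0.593 with an estimated correlation), -0.41 without SG 1, 0.01 without SG 2 and -0.06 without SG 3, the latter pair without a call, and -0.10 without control 2. Genes of endoplasmic reticulum stress and folding had a median of -0.15 (adjusted p = 0.000179; adjusted p = 0.387 with an estimated correlation), -0.05 with no call without SG 1 and -0.31 without SG 2. Of these Edem1, at 117 ± 6.14 CPM in SG and 154 ± 1.11 in control, and the stress kinase Eif2ak3 were lower adjusted over the list alone.

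Fibroblast and matrix genes were lower in SG than in control in 26 of 33 (median -0.21, camera adjusted p = 4.82e-06; adjusted p = 0.387 with an estimated correlation), with 2 members, Ccn2 among them, adjusted over the list alone and medians of -0.14 without control 2 and -0.10 without SG 3. Glucocorticoid-responsive genes had a median of -0.22 (adjusted p = 0.0012; adjusted p = 0.387 with an estimated correlation), -0.12 with no call without control 2 and -0.44 without control 1. Errfi1, Per1 and Tsc22d3 were lower and Zbtb16 higher adjusted over the list alone. Immediate early genes had a median of -0.28 (adjusted p = 3.46e-05; adjusted p = 0.387 with an estimated correlation), and -0.10 with no call without control 3. Mucous acinar genes had a median of -0.35 (adjusted p = 0.00151; adjusted p = 0.364 with an estimated correlation), -0.17 without control 2 and -0.24 with no call without SG 2. Serous acinar genes had a median of -0.05 (adjusted p = 0.0359; adjusted p = 0.365 with an estimated correlation), with no call without control 1 (-0.04) or SG 2 (-0.04) and -0.08, -0.23, -0.25 and -0.11 without control 2, control 3, SG 1 and SG 3.

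Several lists that stood highest in control 2 were lower in SG than in control. Cell cycle genes were lower in 30 of 30 (median -2.22, camera adjusted p = 1.5e-18; adjusted p = 0.371 with an estimated correlation), 21 adjusted over the list alone, and kept the call without control 2 with a median of -0.58. The proliferation marker Mki67 averaged 3.27 ± 0.767 CPM in SG and 19.4 ± 22.7 in control, with 45.5 CPM in control 2. Parotid genes had a median of -2.26 (adjusted p = 9.46e-06; adjusted p = 0.301 with an estimated correlation), -0.65 without control 2 and -5.55 without SG 1, with the call kept. Without control 2 the calls of 7 lists were lost, among them those of respiratory chain and glucocorticoid-responsive genes. B cell genes went from -3.42 (adjusted p = 3.17e-05; adjusted p = 0.474 with an estimated correlation) to 0.17, T and NK cell genes from -1.84 (3.51e-05; adjusted p = 0.474 with an estimated correlation) to 0.12, lymph node genes from -3.08 (7.68e-06; adjusted p = 0.387 with an estimated correlation) to -0.35, adipocyte genes from -1.74 (8.73e-05; adjusted p = 0.464 with an estimated correlation) to -0.15, and plasma cell genes from -0.47 (0.0046; adjusted p = 0.387 with an estimated correlation) to -0.05. Plasma cell genes also lost the call without SG 1 (-0.54) or SG 2 (-0.44). Adjusted over the list alone, 13 B cell, 5 lymph node, 4 adipocyte, 0 T and NK cell and 0 plasma cell genes passed.

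Interferon response genes had a median of -0.03 between SG and control (with a test to the higher side, adjusted p = 0.939) and antigen presentation genes of -0.07 (adjusted p = 0.388). Interferon genes were called higher without SG 2 (0.13), and antigen presentation genes higher without control 2 (0.17) and lower without control 3 (-0.20). Heat shock genes had a median of 0.02 (adjusted p = 0.784) and clock genes of -0.02 (adjusted p = 0.195), the latter called lower without control 2 (-0.11) or SG 3 (-0.08). No panel gene passed in this comparison, with Egf at 1071 ± 253 CPM in SG and 808 ± 244 in control (adjusted p = 0.673) and Klk1 at 29086 ± 4742 and 24714 ± 4075 (0.724).

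A further question is which changes of obesity were reversed after surgery. All 14 genes called in DIO against control had the opposite sign in SG against DIO, and all 14 passed there when adjusted over these genes alone, as 8 did in SG against control, while 0 passed over all genes in either. The part of the change that was undone had a median of 61.3%. It was 92.9% for Dbp, 90.4% for Igtp, 88.4% for Esp8, 83.4% for Hspa8 and 75.0% for Nr1d1, but 38.6% for Ces1d, 38.3% for Zbtb16 and 31.2% for Dgki. Zbtb16 averaged 12.4 ± 9.04 CPM in SG. Genes picked for a difference between the DIO and control libraries tend to differ in any comparison that uses either set again. Chance variation in the shared DIO libraries also gives such genes opposite signs and a share undone. The share expected without an effect of surgery was not computed, so 61.3% does not by itself measure reversal.

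Across all genes, 269 were higher in DIO than in control and lower in SG than in DIO at an unadjusted p under 0.05, against 40.1 for independent lists, and 217 were lower and then higher, against 28.6. The balance of these directions rests on the scaling. With RLE scaling the numbers were 214 and 271, against 29.1 and 39.7 for independent lists. With library totals they were 488 and 59, against 112 and 4.20. Unchanged groups that share the DIO libraries gave 155 genes of opposite sign on average in 100 simulated draws, against 486 observed. These simulated draws hold no effect and the independent lists no shared libraries, and part of the excess may come from the shared DIO libraries, which are too few to be split. The simulated genes were also drawn independently of each other, without the joint shifts of many genes in a real library. The excess over the simulation thus does not by itself show reversal. The correlation of the fold changes across genes, which are not independent replicates, was -0.345, against -0.502 in the simulation, and the covariance -0.0694 against -0.0582, a difference of -0.0113. With edgeR 0 genes were called in both comparisons, where DESeq2 gave 33 and the fit without control 2 gave 63. The correlation was -0.662 without control 2, -0.181 without control 3 and -0.190 without SG 1.

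**Figure D3:**
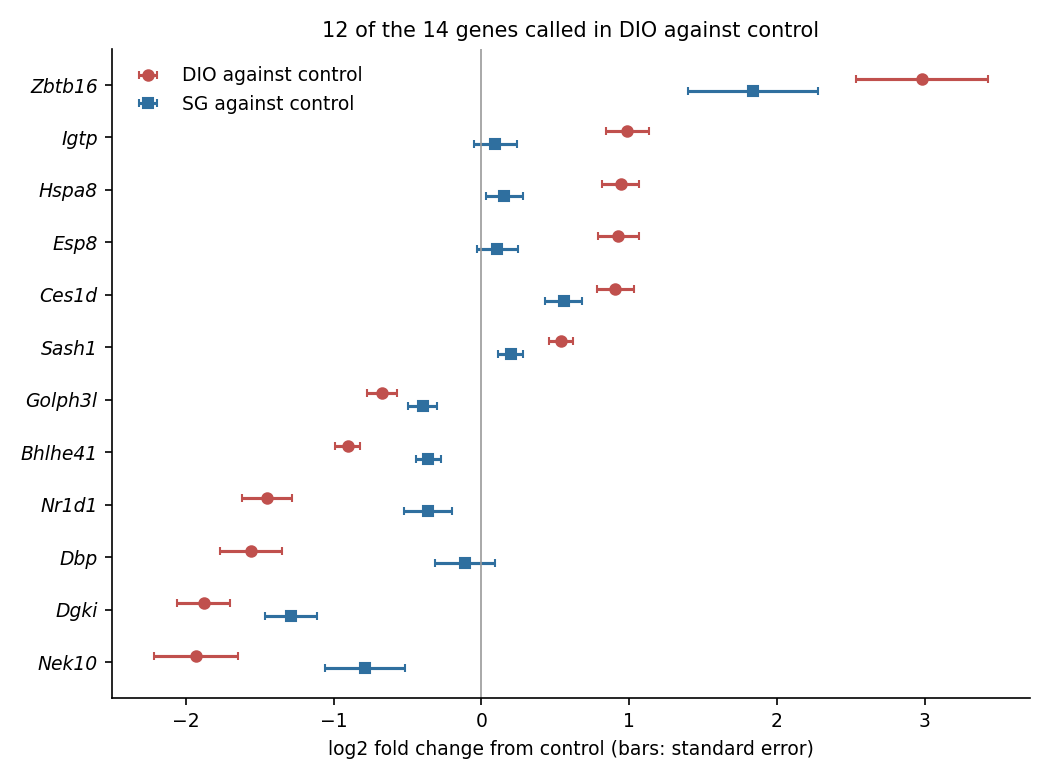
Log2 fold change from control (horizontal axis) of 12 of the 14 genes called in DIO against control, with circles for DIO, squares for SG and bars of 1 standard error. Dbp went from -1.56 in DIO to -0.11 in SG, and Zbtb16 from 2.98 to 1.84.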

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

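Each group held 3 libraries, so single libraries moved many results, and list calls rested on the preset correlation of camera. With an estimated correlation 0 lists were called in each comparison, as with fry (0, 0 and 0) and with the estimated correlation without control 2 (0, 0 and 0). Of 5940 named-gene values under the alternatives, 5542 stayed as they were, called or not called, 112 were weaker, 286 stronger and 0 reversed. Of 1944 list values, 1554 stayed as they were, called or not called, 276 were weaker, 82 stronger and 32 reversed. A changed sign of a value called in neither setting was not counted as a reversal, which left 93 gene values and 75 list values of that kind. The cause of changes with processing was not tested.

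The count of genes changed, DIO against control, was 14, and 185 with DESeq2, 482 in the DESeq2 fit with control 2 left out, 22 with library totals, 37 with no filter, 4 with only the groups compared, 2 with FPKM without a filter, 5 with a minimum 2-fold change, 111 with voom weights, 230 without control 2 and SG 2, 186 with the lymphocyte covariate, 13 without the genes of other tissues, and 0 to 140 with a library left out. For SG against DIO the count of 0 became 80 with DESeq2, 392 with DESeq2 without control 2, 6 with no filter, 179 with only the groups compared, 3 with FPKM without a filter, 14 with voom weights, 5 without control 2 and SG 2, and 0 to 117 with a library left out. For SG against control the count of 0 became 54 with DESeq2, 26 with DESeq2 without control 2, 3 with no filter, 1 and 1 with FPKM at pseudocounts of 1 and 0.1, 3 with FPKM without a filter, 3 with voom weights, 3 with the robust fit, 2 without control 2 and SG 2, 4 with the covariate, and 0 to 6 with a library left out.

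Genes that changed in DIO and changed back in SG numbered 0, and 33 with DESeq2, 227 with DESeq2 without control 2, 4 with no filter, 2 with only the groups compared, 2 with FPKM without a filter, 9 with voom weights, 5 without control 2 and SG 2, and 0 to 63 with a library left out. The correlation of both fold changes ran from -0.662 to -0.181 with a library left out, with an SD of 0.148. Lists called with a library left out numbered 14 to 22, 18 to 26 and 19 to 24 in DIO against control, SG against DIO and SG against control, and 14 in SG against control without control 2 and SG 2. A replicate block gave 18, 0 and 0 genes and a correlation of -0.436. Of 9 same-number correlations, which ran from -0.0934 to 0.307, 3 exceeded 0.1, and 5 of 9 libraries lay closest to their own number. These values do not settle pairing, which the main test left out because the labels name no pairs.

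The direction of list tests turned in these settings, given with the medians. In DIO against control, adipocyte genes had 0.10 without control 2 and SG 2 and 0.10 with the estimated correlation without control 2 (-0.89 to 0.10 with a library left out), lymph node genes 2.14 without control 2 and SG 2 (-1.75 to 2.14), and B cell genes -1.13 to 2.72. In SG against DIO, kallikreins had -0.17 without control 2 and SG 2 and -0.17 with the covariate (-0.17 to 0.29), and skeletal muscle genes -0.0916 to 2.48. With the covariate, duct genes had -0.0460, adipocyte genes 0.29, respiratory chain genes -0.0778, macrophage genes 0.0473, B cell genes 0.55, lymph node genes 0.16 and cell cycle genes 0.69. In SG against control, with control 2 and SG 2 both left out, cholesterol genes had 0.0603, antigen presentation genes 0.23, T and NK cell genes 0.12, B cell genes 0.19, plasma cell genes -0.0159, with the sign of the median kept, and skeletal muscle genes -0.0851. With the covariate antigen presentation genes had 0.14 and B cell genes 0.26, and with the estimated correlation without control 2 T and NK cell genes had 0.12 and B cell genes 0.17. With a library left out the ranges were -0.20 to 0.17 for antigen presentation, -0.11 to 0.36 for macrophage, -2.37 to 0.12 for T and NK cell, -3.99 to 0.17 for B cell and -0.25 to 2.29 for skeletal muscle genes.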

Other observations

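Without control 2, a choice made after the result was seen, some lymphocyte and antigen presentation genes changed in DIO and changed back in SG. Control 2 had the highest mean level of lymphocyte genes (2.47) and control 3, which was kept, the lowest (-2.07). Leaving out control 2 thus by itself favoured a rise of lymphocyte genes in DIO, which is no support for one. Without control 3 instead, the DIO against control medians were -0.22 for T and NK cell genes and -1.13 for B cell genes. Cd3d, a chain of the T cell receptor complex, was 0.453 and 0.170 CPM in control, 3.06, 2.76 and 1.35 in DIO and 0.254, 0.438 and 0.583 in SG (log2 fold change 2.94, SE 0.55, adjusted p = 0.0300, then -2.49, SE 0.45, adjusted p = 0.0352; edgeR, n = 2, 3 and 3). Cd74, the invariant chain of class II antigen presentation, rose by 0.90 (SE 0.15, adjusted p = 0.0205) and then changed by -0.65 (SE 0.13, adjusted p = 0.0433), and H2-Aa by 0.86 (SE 0.14) and -0.60 (SE 0.12). Ltb, a cytokine of lymphoid tissue, rose by 1.75 (SE 0.33, adjusted p = 0.0300) and then changed by -1.45 (SE 0.28, adjusted p = 0.0420). Akna, a factor of lymphocytes, rose by 1.20 (SE 0.23) and then changed by -1.25 (SE 0.20). Fdft1 of cholesterol synthesis fell by 0.85 (SE 0.18, adjusted p = 0.0494) and then rose by 0.85 (SE 0.16, adjusted p = 0.0413). In all, 140 genes changed in DIO and 117 in SG against DIO, which included 10 and 9 of 16 antigen presentation genes, 6 and 9 of 24 T and NK cell genes and 2 and 1 of 14 B cell genes, and 63 changed in both, with the opposite signs that the shared DIO libraries favour.

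Regrouping the libraries tests how often chance alone gives counts as large. Of 10 splits of the control and DIO libraries, 1, the real one, gave as many genes (14, highest other 0) and 1 as many lists (20, highest other 18). For SG against DIO 10 of 10 splits gave as many genes (0, highest other 0) and 2 as many lists (19, highest other 23), and for SG against control 10 gave as many genes (0, highest other 0) and 1 as many lists (23, highest other 22). Any split reaches a count of 0, and 10 splits are too few to give a share under 0.05. At an unadjusted p under 0.05 the real splits gave 1537, 1331 and 1208 genes, and the highest others 2070, 2265 and 2250. Of 100 regroupings of all 9 libraries, 100 had as many genes changed back, which a count of 0 makes certain. In 70 of them the correlation was as negative as -0.345, down to -0.825, and sharing the DIO libraries alone gave -0.502 in the simulation.

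The interferon and antigen presentation tests were written down before their values were seen, other than the median of all genes with library totals, chosen only after the result was seen. The lymphocyte covariate they use was itself chosen after the data were examined. Both lists were higher in DIO and lower in SG, while T, B and NK cell genes differed between libraries. With a covariate for lymphocyte genes the interferon median was 0.46 in DIO against control (100% of 0.46) and -0.40 in SG against DIO (83.9%). The antigen presentation median was 0.44 in DIO against control (74.3%). Within groups the covariate varied mainly between control 2 (2.47) and control 3 (-2.07), against 0.45 to 1.45 in DIO and -1.13 to -0.80 in SG. Its slope thus rested on the control libraries, and these values argue against lymphocyte content only as it varied there. A few abundant genes shift all others alike, but with library totals the median of all genes was 0.10 and -0.0842. The list medians were then 0.56 and -0.58 (interferon) and 0.68 and -0.78 (antigen presentation), which argues against that as the whole cause. The lists lay beyond the median of all genes by 0.46 and -0.50 (interferon) and 0.58 and -0.69 (antigen presentation). Scaling moves all genes nearly alike, so these gaps could hardly change with it and are no further test. Antigen presentation kept -0.35 in SG against DIO (51.0%), too near 50% to decide. The standard error over its 16 members was 0.04, which treats the genes as independent and does not measure the spread between libraries. Lymphocyte content of the DIO and SG libraries thus stays open for both lists. A response of gland cells to interferon, which might account for both lists, was not tested.

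For the clock genes the test of collection time and its sets of genes were chosen only after the result was seen. Dbp, Nr1d1 and Bhlhe41 fell in DIO, and the clock genes called had a median size of 1.20 with the lymphocyte covariate against 1.18 without it. As that covariate varied mainly among the control libraries, this argues against lymphocyte content only as it varied there. The 6 genes set to peak with Bmal1 had a median of 0.49 and the 8 set to peak opposite to it -0.42, a difference of 0.92. Both sets turned in SG against DIO (-0.47 and 0.24). The second left out Per1 and Per2, and had -0.28 and 0.19 with them. Neither set held the clock list members Cry2, Bhlhe40 and Rora. The libraries' times of collection are not given in the sources used here, so a difference in the time of day stays open. A shift of the gland's clock by diet might give the same values, which was not tested.

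For control 2 both tests were chosen only after the result was seen. Amy1, Dnase1, Bpifa2, Prpmp5 and Prb1, genes of the parotid gland, were highest in control 2, and the lowest correlation between any pair of them over the libraries was 0.898. Neighbouring tissue in that sample could give this and stays open, with lymph node genes at 3.17 and adipocyte genes at 1.79 above the gene means. All members of the lymph node list too low to be tested were also highest in control 2. Among them, Glycam1 had 2150 counts there and 0 to 23 in the other libraries, and Prox1 98 and 1 to 11. These values go with lymph node tissue in that sample, which the labels do not mention. Its total lay 1.12% above that of the nearest library, which argues against depth. Serous acinar genes stood at 0.07 there against 0.15 and 0.10 in control 1 and control 3, and no biological explanation was tested.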
